A study of Drosophila melanogaster with 9 samples.

How the data were processed

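Messenger RNA from whole flies was sequenced in 9 libraries, after Trizol extraction and a TruSeq kit with polyA selection, per the labels' protocols. The authors deposited 3 tables, 1 for each pairwise comparison of the groups. Raw read counts per gene are deposited for each library, per the file headers, and these counts were used here. The tables also hold the authors' log2 fold changes (a moderated and an unmoderated one) and the authors' p-values with their adjusted p-values, per the file headers; these are reported only as the authors' deposited values. A further 18 columns of the authors' normalised values were not used here. Novoalign and DESeq, with no versions, and the build dm3 are named in the submitters' processing notes. How multiply mapped reads and strand were treated is not given in the sources used here, so values of near-identical or overlapping genes are uncertain. The deposited tables give identifiers and symbols without positions, and the reference annotation at hand is of another build, so no coordinates are printed; its exon lengths were used as a gene property.

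Columns were assigned to libraries by the library code that each sample's description and the column name share. Counts of a library in different tables were identical (0 values differed). The tables list 13073, 13087 and 13111 genes, and the 13140 genes with counts in all 9 libraries were analysed. Totals were 21777434 to 28166388 counts per library. No pair of libraries agreed within counting noise: the chi-square statistic per gene of a pair, for genes with a mean of at least 50 counts, was at least 3.28, where about 1 is expected for copies. Of the identifiers, 12627 were found in the reference name table.

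Counts were fitted with edgeR 4.0.16 (TMM normalisation, filterByExpr by group, robust quasi-likelihood fit and F-test) in R 4.3.3 over all 9 libraries with 3 groups and no covariate. Contrasts were GP/P against WT, GP/M against WT, GP/P against GP/M, and both lines together against WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change over the square root of F, and 95% intervals follow from them. Levels are normalised CPM, and log2 CPM used a prior count of 2. Differences within a set compare libraries of the same replicate number.

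The 29 gene lists, the groups, the main design and the alternatives were fixed before the data were examined. The lists held 839 matched members, and 32 members were unmatched. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the lists of a comparison. fry tests whether a list's genes move one way on balance and does not compare the list with other genes. Named genes followed a fixed rule. It takes the 10 largest changes in each direction among genes past the threshold or, where fewer than 10 pass, the 10 smallest p. It adds at most 1 member of a list by p where none passes, AkhR, Akh, bmm and Hsl always, and for genes shared by both lines the 10 with the smallest larger p. List members are named here for lists called with or without the block.

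The replicate number was taken to pair the libraries, since the labels tie a set of samples to each experiment and the column names carry a set code shared by the libraries of a number. As a check, deviations from the group means were correlated across genes: same-numbered libraries gave r of 0.066 to 0.293, with 8 of 9 pairs over 0.1, and other pairs -0.267 to 0.027. Each of the 9 libraries correlated best with one of its own number. The common biological coefficient of variation was 6.56% without and 4.36% with the replicate block. The deposited p-values follow a blocked fit most closely: DESeq2 with the block on the 6 libraries of a comparison had Spearman correlations with them of 0.9953, 0.9928 and 0.9946 across genes, against 0.9741, 0.9633 and 0.962 without it. This fit was added after the data were seen.

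Alternatives were other size factors, other filters, DESeq2 1.42.0, limma-voom, the replicate block, only the groups compared, stricter thresholds and leaving out each library. Fits that left out a library had no block. The scripts were tested on simulated data: counts drawn from the means, library sizes and dispersions (without the block) of these libraries. Libraries were drawn independently, with no difference between sets. For the pairwise comparisons 200 genes were changed in GP/P and another 200 in GP/M, and for both lines together 200 genes in both. Recovery with fewer changed genes was not simulated. Shared controls were simulated 100 times with unchanged groups. For a check on gene length, a loess trend (span 0.5) of each library's log2 CPM on exon length was removed. An exon length was found for 96.1% of the tested genes.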

Results

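RNA was sequenced from whole adult Drosophila melanogaster of the Canton S background, all wild-type in genotype and 10 to 11 days old. The 9 libraries fell into 3 groups of 3. The control group is called WT. The GP/P and GP/M groups were F2 descendants of obese grandfathers, and the series names mutants of AkhR, the receptor of adipokinetic hormone, as the origin of the obesity. Descent ran through the F1 father in GP/P and through the F1 mother in GP/M. The comparisons ask whether flies that carry no mutation themselves differ in transcript levels from controls when a grandfather was obese, and whether the sex of the F1 parent matters. Total gene counts ranged from 21777434 to 28166388 per library over 13140 genes, and 12913 genes passed the filter on low counts. The labels describe the replicates as independent both biologically and experimentally, with a set of libraries for each experiment, so libraries with the same replicate number are called a set here. The first principal component held 25.4% of the variance in log2 CPM, counts scaled to the library size. On it the 3 set 3 libraries lay between 7.59 and 13.01, the set 1 libraries between -13.23 and -2.90, and the set 2 libraries between -4.85 and -0.35.

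**Figure D1:**
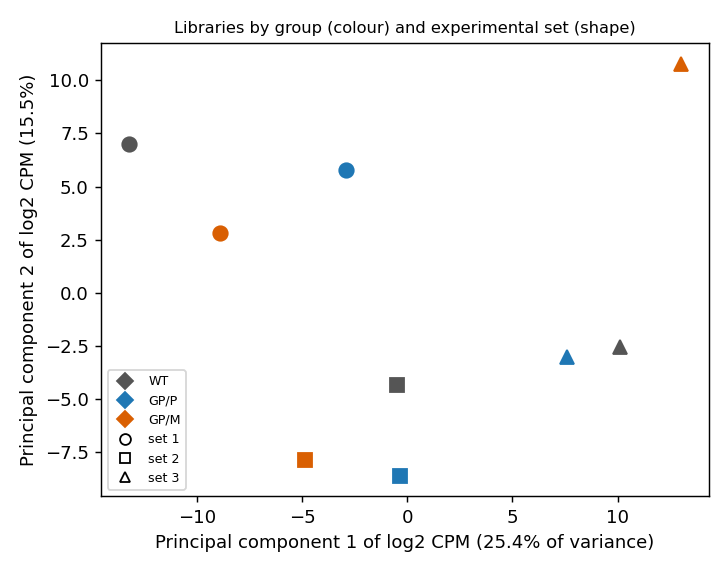
Each point is 1 of the 9 libraries on the first and second principal components of log2 CPM, coloured by group, with circles for set 1, squares for set 2 and triangles for set 3. The first component held 25.4% and the second 15.5% of the variance, the set 3 libraries lie above all others on the first component, and the ranges of sets 1 and 2 overlap.

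Neither the gene named for the forebears' mutation nor 3 genes of fat mobilisation passed the test in any comparison. AkhR (FBgn0025595, deposited under the symbol GRHR) was at 85.4 ± 7.56 CPM in WT (SD, n = 3), 85.3 ± 7.68 in GP/P (SD, n = 3) and 86.0 ± 11.1 in GP/M (SD, n = 3). The 95% interval of its fold change ran from 0.86 to 1.16 for GP/P against WT and from 0.87 to 1.17 for GP/M against WT. Akh, the peptide hormone that mobilises stored fat, was at 12.5 ± 0.344 CPM in WT, 11.8 ± 0.601 in GP/P and 11.3 ± 1.07 in GP/M (SD, n = 3 each). The triglyceride lipase gene bmm was at 150 ± 11.4, 156 ± 22.3 and 155 ± 16.4 CPM in the same order. The hormone-sensitive lipase gene Hsl (FBgn0034491, deposited as CG11055) was at 69.4 ± 2.39, 71.6 ± 1.19 and 70.0 ± 1.45 CPM. All 4 genes had an adjusted p of 1 in each comparison by edgeR's quasi-likelihood test.

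For flies descended through the father, GP/P against WT, no gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test among 12913 genes. At an unadjusted p under 0.05 there were 2.59% of the genes, fewer than the 646 genes expected by chance, and limma-voom and DESeq2 called 0 genes as well (337 and 163 at the unadjusted level). With the replicate number as a block, 885 genes (6.85%) had an unadjusted p under 0.05, above the 646 expected, and none passed. DESeq2 with the block on all 9 libraries called 1 gene, CG43319 (adjusted p = 0.00966; 1 by edgeR without the block). The 10 genes with the smallest p all had an adjusted p of 1. CG43319 (FBgn0263024) was at 80.4 ± 6.06 CPM in GP/P and 103 ± 11.3 in WT (SD, n = 3 each), 0.78-fold with a 95% interval in log2 of -0.52 to -0.20, and lower in 3 of 3 sets. CG12772 was at 1.19-fold (25.5 ± 0.70 against 21.5 ± 0.821 CPM), higher in 3 of 3 sets. Of the others, CG9866 and Myo10A, a myosin gene, were at 1.17-fold and 1.19-fold of WT. The phosphatidylinositol transfer gene rdgBbeta was at 0.81-fold, CG43798 at 0.78-fold, CG43165 at 0.73-fold, CR43784 at 0.82-fold, CG4884 at 0.83-fold and CG5778 at 0.85-fold. The precision was high for most genes: 97.4% of the 11811 genes with a mean log2 CPM of at least 1 had a 95% interval that lay within 1.5-fold of WT on both sides. In counts simulated for this comparison, the test recovered 91.0% of genes changed 1.5-fold and 47.8% of genes changed 1.25-fold.

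Of the 29 gene lists fixed beforehand, 4 were called for GP/P against WT by camera with a preset correlation of 0.01 between genes. The male accessory gland list, genes of seminal fluid proteins, was lower, with 50 of 54 members below WT and a median of 0.939-fold (adjusted p = 9.47e-16; adjusted p = 0.789 with an estimated correlation). Its member with the smallest p was Sfp70A4, at 38.1 ± 1.4 CPM against 44.4 ± 4.09 (SD, n = 3 each). In this list the difference was not present in set 3, where the median of GP/P minus WT was 0.023 in log2, against -0.187 in set 1 and -0.118 in set 2. Over all members the median was -0.091, and without WT 1 or WT 3 it was -0.048 or -0.162, with the list still called. The list of antimicrobial peptides and peptidoglycan recognition was lower, with 25 of 27 members below WT and a median of 0.871-fold (adjusted p = 5.14e-05; adjusted p = 0.789 with an estimated correlation). Its leading member by p, the recognition protein gene PGRP-SD, was at 16.1 ± 2.85 against 19.1 ± 1.46 CPM. The median of GP/P minus WT in this list was 0.073 in set 1, -0.298 in set 2 and -0.361 in set 3. Muscle genes (19 of 25 above WT, median 1.027-fold) and glycolysis genes (15 of 16 above WT, median 1.029-fold) were higher, each with an adjusted p of 0.0114 and of 0.789 with an estimated correlation. Strn-Mlck, a myosin light chain kinase of muscle, was at 1.12-fold and the aldolase gene Ald at 1.06-fold. In sets 1, 2 and 3 the median of GP/P minus WT was 0.05, 0.024 and 0.048 for muscle and 0.042, 0.046 and 0.043 for glycolysis genes. After a trend with gene length was removed from each library, the accessory gland median went from -0.09 to -0.044 and the antimicrobial median from -0.218 to -0.171, both still called (adjusted p = 8.50e-05 and 0.0461), and the glycolysis call ended (adjusted p = 0.105, against 0.0276 before among members with an exon length). Its median did not shrink, at 0.034 against 0.03 in log2, with a member SD of 0.03 and 0.029. Among the genes with an exon length the muscle list was not called before or after (adjusted p = 0.0582 and 0.124), and the TCA cycle and respiratory chain list was not called before but was called after, as higher (0.00224). No member of any list passed over all genes or adjusted over the list alone. With the replicate number as a block, the count of genes stayed at 0 (885 at an unadjusted p under 0.05), while 14 members of 6 lists passed adjusted over the list alone and 12 lists were called. The 8 lists that the block added were the chromatin modifiers (adjusted p = 0.0463), circadian clock (0.0113), fatty acid synthesis (0.0369), heat shock protein (0.0196), hemocyte (0.0369) and trehalose, glycogen and gluconeogenesis (0.0433) lists, which were higher, and the cytochrome P450 (0.0433) and ribosomal protein (0.00534) lists, which were lower. Without the block, removal of the length trend took the ribosomal median from -0.016 to 0.01. Medians shrank from 0.049 to 0.02 for chromatin modifiers, 0.049 to 0.014 for fatty acid synthesis, 0.062 to 0.025 for hemocyte and 0.034 to 0.021 for heat shock genes. The circadian, trehalose and cytochrome P450 medians went from 0.072, 0.025 and -0.012 to 0.057, 0.023 and -0.02. With the block and an estimated correlation, or with fry, no list was called, the smallest adjusted p being 0.318 and 0.0959. In those lists the members with the smallest p were ph-p (1.12-fold), per (1.09-fold), Zw, the glucose-6-phosphate dehydrogenase gene (1.10-fold), Hsp83 (1.08-fold), nimC2 (1.18-fold), Pepck (1.08-fold), Cyp6a14 (0.81-fold) and RpL39 (0.92-fold). In the authors' deposited table no gene had an adjusted p under 0.05 for this comparison, and CG43319 and CG42852 were nearest, both at 0.0619. CG42852, chosen after its values were seen, was at 126 ± 6.46 CPM in GP/P and 157 ± 26.8 in WT, and its log2 fold change of -0.32 was -0.176 without WT 2. Without WT 3, edgeR called 1 gene, the glutathione transferase gene GstD2 (0.34-fold, adjusted p = 0.00166), and the glycolysis call was lost without any 1 of WT 1, GP/P 2 and GP/P 3 (medians 0.027, 0.022 and 0.037; adjusted p = 0.0797, 0.13 and 0.0813). The muscle call was lost without WT 2 or GP/P 3 (medians 0.027 and 0.036, against 0.038; adjusted p = 0.0664 and 0.0683), and 10, 17 and 8 lists were called without WT 1, WT 3 and GP/P 1. The glycolysis median was 0.068 without GP/P 1, against 0.042 with it. The ribosomal list, not called with all libraries and no block (median -0.012, adjusted p = 0.0582), was called as higher without WT 1 (0.033, adjusted p = 0.0164). It was called as lower without WT 3 (-0.069, adjusted p = 6.02e-13), GP/P 1 (-0.032, 0.00122), GP/P 2 (-0.028, 0.00761) or GP/M 3 (-0.016, 0.0432). Amylases and maltases (-0.106 and 0.076) and neuron genes (-0.058 and 0.052) were called as lower without WT 1 and as higher without WT 3, and the TCA list was called as higher without WT 1 (0.03, adjusted p = 0.0167). The fits without 1 library had no block, so they left the groups uneven over the sets. For set 3 minus set 1 the medians were -0.155 for ribosomal, 0.213 for amylase and maltase and 0.185 for neuron genes. The moves of these lists without WT 1 or WT 3 ran the way that such unevenness brings, so library and set cannot be told apart. Single libraries moved several named genes by over 1.5 times in log2. Without WT 1, per went from 0.119 to 0.006, ph-p from 0.166 to 0.088, Hsp83 from 0.113 to 0.058, Strn-Mlck from 0.166 to 0.09, Pepck from 0.108 to 0.062, RpL39 from -0.125 to -0.078 and CR43784 from -0.293 to -0.175. Without GP/P 2, nimC2 went from 0.237 to 0.125, per to 0.06 and Hsp83 to 0.06. PGRP-SD went from -0.249 to -0.397 without GP/P 1 and -0.155 without GP/P 3, per to 0.241 without WT 2, and RpL39 to -0.193 without WT 3.

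For flies descended through the mother, GP/M against WT, no gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 198 genes, and limma-voom and DESeq2 called 0 genes (200 and 78 at the unadjusted level). Among the 10 genes with the smallest p, all with an adjusted p of 1, CG10863 was the most abundant, at 268 ± 8.5 CPM in GP/M and 302 ± 8.7 in WT (SD, n = 3 each). It was at 0.89-fold and lower in 3 of 3 sets. CG34423 was at 1.36-fold (15.8 ± 3.05 against 11.7 ± 0.179 CPM), CG9192 at 1.37-fold and CG13321 at 1.13-fold, each higher in 3 of 3 sets. CG13827 was at 0.85-fold, CG14529 at 0.74-fold, CG3548 at 0.81-fold and CG6066 at 0.77-fold. CG43440 and CG13748 were at 0.63-fold and 0.41-fold and were scarce, at 2.21 and 0.666 CPM in WT. As for the father's line, 97.4% of the 11811 genes with a mean log2 CPM of at least 1 had an interval within 1.5-fold. The simulated recovery for this comparison was 85.1% at 1.5-fold and 46.3% at 1.25-fold.

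Camera with the preset correlation called 4 lists for GP/M against WT. The Turandot and JAK-STAT list, stress-induced humoral factors and cytokine signalling genes, was higher, with 8 of 11 members above WT and a median of 1.197-fold (adjusted p = 5.62e-04; adjusted p = 0.748 with an estimated correlation). TotX, its member with the smallest p, was at 42.9 ± 2.4 CPM against 36.1 ± 4.64 (SD, n = 3 each). The ovary and eggshell list was lower, with 8 of 11 members below WT and a median of 0.893-fold (adjusted p = 0.0125; adjusted p = 0.462 with an estimated correlation). Its members were scarce: the chorion gene Cp18 was at 0.566 ± 0.0919 CPM in GP/M and 0.936 ± 0.19 in WT. The male accessory gland list was lower (42 of 54 members below WT, median 0.97-fold, adjusted p = 2.56e-04) and muscle genes were higher (19 of 25 above WT, median 1.027-fold, adjusted p = 0.0125). With an estimated correlation these adjusted p were 0.997 and 0.748. Sfp96F was at 0.86-fold and the flight muscle actin gene Act88F at 1.22-fold. No member of any list passed over all genes or adjusted over the list alone. With the replicate block, the count of genes stayed at 0 (452 at an unadjusted p under 0.05), 4 members of 2 lists passed adjusted over the list alone, and 7 lists were called. The 3 lists that the block added were the heat shock proteins, higher (adjusted p = 0.0265), and the amylases and maltases (0.00565) and ribosomal proteins (6.07e-04), both lower. Without the block, removal of the length trend took their medians from 0.024, -0.038 and -0.02 to 0.027, -0.04 and -0.012. With the block the smallest adjusted p was 0.421 under an estimated correlation and 0.26 under fry. The leading members there were Hsp23 (1.08-fold), the maltase gene Mal-B2 (0.94-fold) and RpS21 (0.93-fold). The accessory gland call was lost without WT 1, WT 2 or GP/M 3 (medians -0.002, -0.022 and -0.01, against -0.044; adjusted p = 0.708, 0.2 and 0.252), as was the muscle call (medians 0.029, 0.033 and 0.005, against 0.038; adjusted p = 0.14, 0.108 and 0.332). The Turandot call was lost without WT 2 or GP/M 3 (medians 0.167 and 0.272, against 0.26; adjusted p = 0.108 and 0.0764) and the ovary call without WT 3 (median -0.159, against -0.163; adjusted p = 0.0892). GstD2 was called without WT 3 (0.42-fold, adjusted p = 0.016). The count of lists was 8 without WT 1, GP/M 1 or GP/M 3, 1 without WT 2 and 10 without GP/M 2. The ribosomal list, not called with all libraries and no block (median -0.019, adjusted p = 0.0634), was called as higher without WT 1 (0.032, adjusted p = 0.00573) or GP/M 3 (0.03, adjusted p = 0.0101). It was called as lower without WT 3 (-0.073, adjusted p = 2.09e-16), GP/M 1 (-0.052, 5.76e-08) or GP/M 2 (-0.03, 0.00415). The chromatin modifiers were called as lower without WT 1 (-0.043) and as higher without WT 3 (0.069). Of the named genes, CG34423 went from 0.443 to 0.274 in log2 without GP/M 3, Sfp96F from -0.211 to -0.1 without WT 2, Mal-B2 from -0.088 to -0.052 without WT 3 or GP/M 1, and RpS21 from -0.105 to -0.031 without WT 1 and -0.18 without WT 3. Act88F went from 0.29 to 0.132, 0.461 and 0.181 without WT 2, WT 3 and GP/M 3. Of the medians that stayed called, accessory gland moved from -0.044 to -0.099 and -0.07 without WT 3 and GP/M 2, muscle from 0.038 to 0.022 without WT 3, and ovary from -0.163 to -0.251, -0.323 and -0.274 without WT 1, WT 2 and GP/M 3. On genes with an exon length the muscle list was not called (adjusted p = 0.065). The antimicrobial peptide list, not called with all libraries (median 0.047, adjusted p = 0.118), was called as higher without GP/M 1 or GP/M 2 (medians 0.263 and 0.095) and as lower without GP/M 3 (-0.091, adjusted p = 0.0394).

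Among the values of the authors' deposited table, 4 genes had an adjusted p under 0.05 for GP/M against WT, all higher in GP/M. They are TotC (adjusted p = 1.51e-06), TotA (1.95e-06), ACC, the gene of acetyl-CoA carboxylase in fatty acid synthesis (0.00802), and h, which encodes the transcriptional repressor Hairy (0.00853). Their moderated fold changes in the authors' deposited table were 1.19, 1.17, 1.13 and 1.13. These genes were chosen after their values were seen. In the counts, TotA was at 455 ± 99.6 CPM in GP/M and 359 ± 64.5 in WT (SD, n = 3 each), and TotC at 178 ± 46.8 and 132 ± 26.9. ACC was at 668 ± 142 and 550 ± 90.5 CPM, and h at 156 ± 24.6 and 127 ± 15.3. Each was higher in GP/M in 3 of 3 sets, and the 95% interval of each log2 fold change by edgeR without the block included 0. These SDs and intervals contain the spread between sets. The log2 fold changes moved when single libraries were left out of edgeR fits without the block. Such fits leave the groups uneven over the sets, so library and set cannot be told apart in these moves. TotC went from 0.425 to 0.272 without WT 2 and 0.211 without GP/M 1, TotA from 0.342 to 0.199 and 0.208 without the same libraries. ACC went from 0.282 to 0.426 without WT 3 and 0.099 without GP/M 3, and h from 0.294 to 0.183 without GP/M 3. TotA and TotC are related genes, so reads shared between them may have been split by the counting. A DESeq2 fit with the replicate block to the 6 libraries of these groups called these 4 genes, and the same model fitted to all 9 libraries called 0 genes, with an adjusted p of 1 for each of the 4. The unadjusted p of that DESeq2 fit to all 9 libraries were 0.0269 for TotC, 0.0769 for TotA, 0.0169 for ACC and 0.0244 for h.

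**Figure D2:**
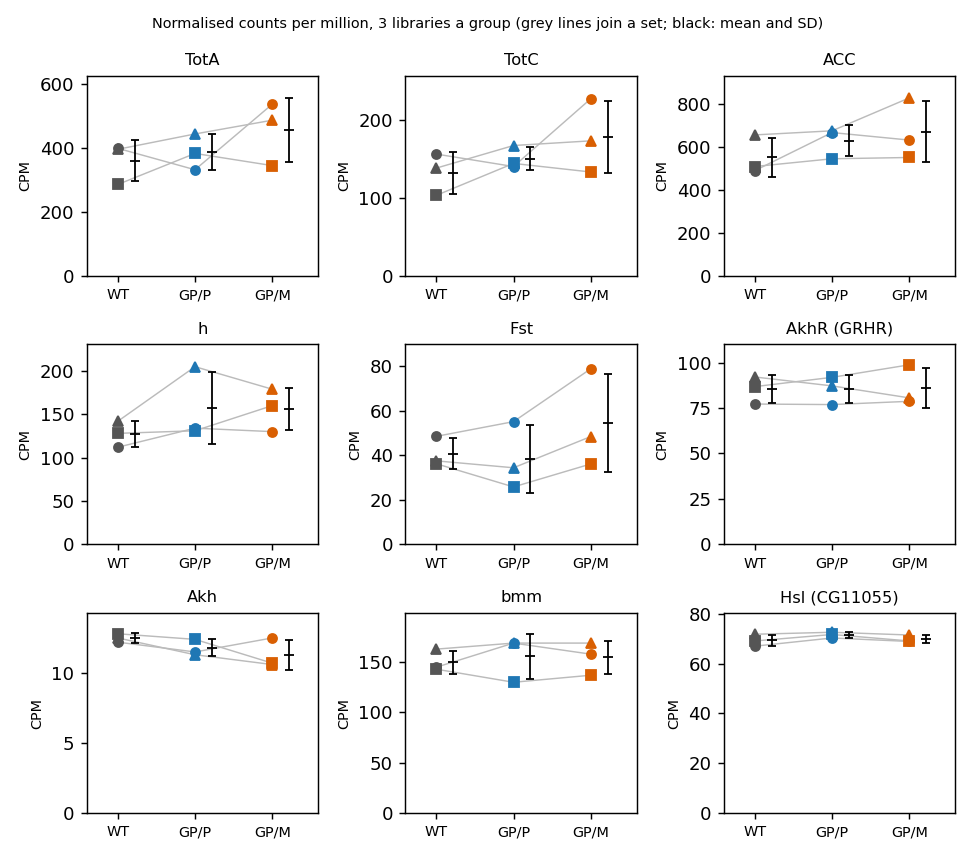
Normalised CPM of 9 genes in each of the 9 libraries, with circles for set 1, squares for set 2 and triangles for set 3, grey lines that join the libraries of a set and black marks for the mean and SD of a group (n = 3). TotA, TotC, ACC and h, chosen after their values were seen, were higher in GP/M than in WT in 3 of 3 sets. AkhR lay near 85 CPM in every group.

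For both lines together against WT, 6 libraries against 3, no gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test. The unadjusted count was 260 genes, limma-voom and DESeq2 called 0 genes (256 and 129 unadjusted), and the smallest adjusted p with the replicate block was 0.193, for CG10863. With the block 655 genes (5.07%) had an unadjusted p under 0.05 by edgeR, against 646 expected by chance. CG10863 was at 269 ± 6.05 CPM in the descendants (SD, n = 6) and 302 ± 8.7 in WT (SD, n = 3), lower in 6 of 6 comparisons within a set. CG34423 was at 1.31-fold and CG9192 at 1.34-fold, both higher in 6 of 6. CG5897 and CR43784 were at 0.57-fold and 0.84-fold, lower in 6 of 6. CG43319 was at 0.85-fold, CG14529 at 0.80-fold, CG42821 at 0.80-fold and CG13516 at 0.87-fold, lower in 5 of 6. Both lines share the 3 WT libraries, so the 6 comparisons are not independent. The genes were also picked by p in this same contrast, which favours agreement of sign. GstD2 was at 3.19 ± 0.47 CPM against 6.7 ± 3.33, with 9.78, 7.15 and 3.18 CPM in WT 1, WT 2 and WT 3. It was called without WT 3 (0.37-fold, adjusted p = 8.57e-04). For this comparison 98.5% of genes with a mean log2 CPM of at least 1 had an interval within 1.5-fold, and the simulated recovery was 89.6% at 1.5-fold.

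For both lines together, camera with the preset correlation called 6 lists, and none with an estimated correlation, where the smallest adjusted p was 0.744. The male accessory gland list was lower (49 of 54 members below WT, median 0.952-fold, adjusted p = 1.77e-12), as was the ribosomal protein list (72 of 93, 0.988-fold, 0.026). The muscle list was higher (20 of 25 above WT, 1.023-fold, 0.00422), as were the Turandot and JAK-STAT list (7 of 11, 1.152-fold, 0.00448), the glycolysis list (15 of 16, 1.02-fold, 0.0319) and the heat shock protein list (12 of 16, 1.025-fold, 0.0319). Leading members by p were Sfp96F (0.84-fold), RpS21 (0.93-fold), Strn-Mlck (1.10-fold), the JAK-STAT ligand gene upd3 (1.85-fold, at 0.34 CPM in WT), Ald (1.04-fold) and Hsp23 (1.07-fold). With the replicate block the circadian clock (adjusted p = 0.0239, higher), hemocyte (0.0357, higher) and cytochrome P450 (0.0239, lower) lists were also called, led by Clk (1.08-fold), nimC2 (1.20-fold) and Cyp301a1 (0.86-fold). The block with an estimated correlation left none (smallest adjusted p 0.363). With the block, 10 members of 5 lists passed adjusted over the list alone, and none did without it. The metabolic lists that were not called with all libraries had these medians in log2: 0.023 for AKH signalling and lipid droplet genes, 0.017 for fatty acid synthesis, 0.026 for fatty acid beta-oxidation, 0.021 for digestive lipases and 0.014 for digestive serine proteases. The median was -0.026 for amylases and maltases, 0.013 for trehalose, glycogen and gluconeogenesis, -0.009 for insulin and TOR signalling, 0.006 for the TCA cycle and respiratory chain and 0.02 for glutathione and UDP-glycosyl transferases. Other uncalled lists were chromatin modifiers (median 0.029), small RNA pathways (0.002), testis (-0.004), neuron (-0.01), photoreceptor (0.012), fat body (0.015), cuticle and oenocyte (0.012), odorant-binding proteins (-0.014), ovary and eggshell (-0.115) and antimicrobial peptides (-0.052). The mean over members had the other sign from the median for the neuron (0.008), small RNA (-0.025) and TCA cycle (-0.001) lists, and camera's direction was down for the cuticle and oenocyte and small RNA lists. The ribosomal list was called as higher without WT 1 (median 0.031, adjusted p = 0.00422), and its call was lost without WT 2, GP/P 3 or GP/M 3 (medians -0.01, -0.001 and 0.005; adjusted p = 0.308, 0.649 and 0.674). The Turandot call was lost without WT 2 (median 0.059, against 0.204; adjusted p = 0.308). The glycolysis call was lost without WT 1, GP/P 2, GP/P 3, GP/M 2 or GP/M 3 (medians 0.01, 0.019, 0.026, 0.023 and 0.024; adjusted p = 0.297, 0.151, 0.093, 0.112 and 0.0612). The heat shock call was lost without WT 3, GP/P 1, GP/P 2 or GP/M 1 (medians 0.017, 0.028, 0.033 and 0.031, against 0.035; adjusted p = 0.435, 0.112, 0.103 and 0.162). Without WT 3, 11 lists were called, among them, as higher, AKH signalling and lipid droplet (median 0.058, adjusted p = 0.0146), trehalose, glycogen and gluconeogenesis (0.068, 0.0373), chromatin modifiers (0.075, 0.00192), fat body (0.045, 0.0288), hemocyte (0.075, 0.0373) and neuron (0.053, 0.0254). Without WT 1 the amylases and maltases (-0.114, adjusted p = 5.09e-06), neuron (-0.067, 0.0096) and cytochrome P450 (-0.026, 0.0387) lists were called as lower and the digestive serine proteases (0.043, 0.00649) as higher. The ovary list was called as lower without WT 2 (-0.22, 0.00762), and the antimicrobial list without GP/P 1 (-0.064, 0.00648) or GP/M 3 (-0.148, 3.65e-06). The cytochrome P450 list was also called as lower without WT 2, GP/P 3 or GP/M 3, the circadian clock list as higher without WT 2, GP/P 1 or GP/M 1, and the hemocyte list as higher without GP/M 1. Of the medians that stayed called, accessory gland moved from -0.071 to -0.03 without WT 1 and -0.126 without WT 3, muscle from 0.033 to 0.015 without WT 1, glycolysis from 0.028 to 0.043 without WT 2 or GP/P 1, and ribosomal from -0.017 to -0.072 and -0.035 without WT 3 and GP/M 1. Of the named genes, CR43784 went from -0.248 to -0.128 without WT 1, GstD2 from -1.096 to -0.714 without WT 1, and CG43319 from -0.242 to -0.159 and Sfp96F from -0.259 to -0.15 without WT 2. RpS21 went from -0.107 to -0.034 and -0.184 and Strn-Mlck from 0.144 to 0.069 and 0.226 without WT 1 and WT 3, upd3 from 0.884 to 0.549 without GP/M 3, and Clk from 0.105 to 0.165 and 0.052 without GP/M 2 and GP/M 3.

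On genes with an exon length, the trend with gene length was removed from each library for both lines together as well. The glycolysis call ended (adjusted p = 0.0393 before and 0.154 after, median 0.031 and 0.023, member SD 0.023 and 0.025), with a smaller median. The ribosomal call ended (0.0277 and 0.924, median -0.02 and -0.001, member SD 0.034 and 0.03), with a median near 0 afterwards. The muscle call ended (0.0229 and 0.0688) with hardly any change of the median (0.032 and 0.03, member SD 0.069 and 0.065). The accessory gland median shrank from -0.071 to -0.039 (adjusted p = 5.51e-12 and 1.18e-04) and the Turandot median went from 0.204 to 0.238 (0.00607 and 0.0332). Both were still called with the preset correlation, while with an estimated one no list was called even before the removal (smallest adjusted p 0.744), and the heat shock list was not called before or after (adjusted p = 0.0645 and 0.0796). Of the lists that only the block called, the hemocyte median shrank from 0.066 to 0.032 without the block. The circadian clock median went from 0.045 to 0.035 and the cytochrome P450 median from -0.017 to -0.02.

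**Figure D3:**
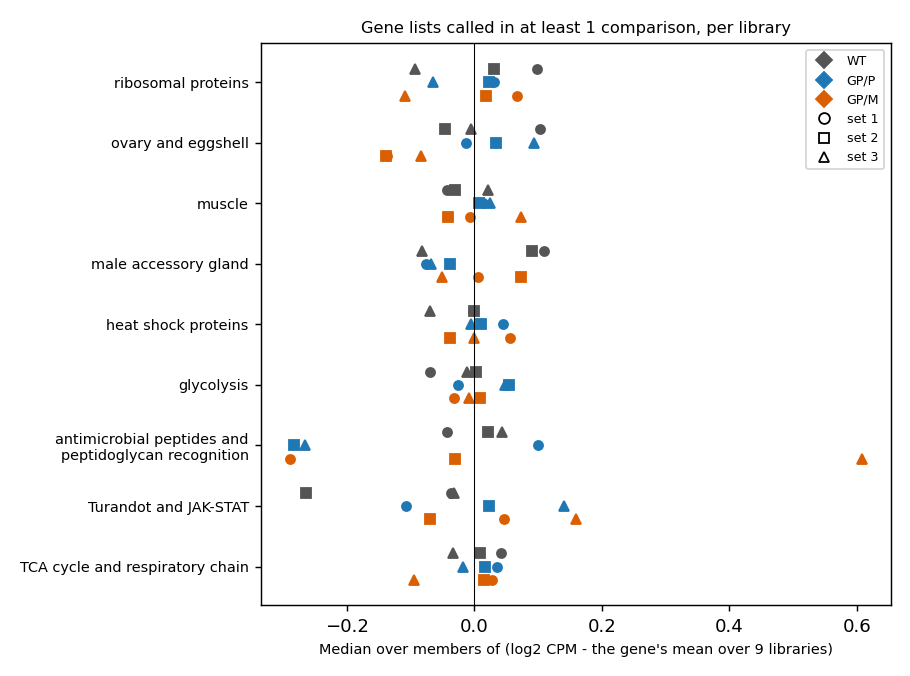
For each of the 9 gene lists called in at least 1 comparison, the horizontal axis gives the median over members of log2 CPM minus the gene's mean over the 9 libraries, 1 point per library, coloured by group and shaped by set. The antimicrobial list reached 0.608 in GP/M 3, and the accessory gland list was at 0.109 and 0.09 in WT 1 and WT 2 but at -0.082 in WT 3.

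No gene was called in both GP/P and GP/M against WT. The fold changes of both comparisons correlated across the 11811 genes with a mean log2 CPM of at least 1 (Pearson's r = 0.475 across genes, which are not independent replicates). Unchanged groups were simulated against the same WT libraries with the dispersions of the blocked fit. They gave a mean r of 0.509 over 100 simulations, with a range of 0.477 to 0.536. The observed variances of the fold changes lay outside the simulated ranges. They were 0.00793 for GP/P (0.00667 to 0.00761 simulated) and 0.00622 for GP/M (0.0067 to 0.00765 simulated). An r below the range therefore cannot be read as a result about the groups. The observed covariance was 0.00334 and the simulated mean 0.00359, or 0.00535 with the dispersions of the fit without the block. The share of genes with the same sign was 67.3%, against 67.0% simulated. At an unadjusted p under 0.05 in both with the same sign there were 40 genes, and independent lists would share 0.9 higher and 1.7 lower genes, a value that leaves out the shared controls. Of the other splits drawn, 14 had 1 library of each set in each group and kept shared controls. They gave 23 to 82 such genes, so 40 does not stand out. The controls are too few to be split. The 10 genes with the smallest larger p of both comparisons are given for GP/P against WT. CG10863 (0.90-fold), CG5897 (0.57-fold), CG42821 (0.78-fold), CG18619 (0.88-fold, in log2 -0.186 and -0.11 without WT 1) and CG6770 (0.91-fold) lay below WT, and CG34423 (1.26-fold), CG9192 (1.30-fold), the homeobox gene ara (1.20-fold), CG13096 (1.12-fold) and mt_tRNA_R (2.47-fold, at 0.168 CPM in WT) lay above it.

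**Figure D4:**
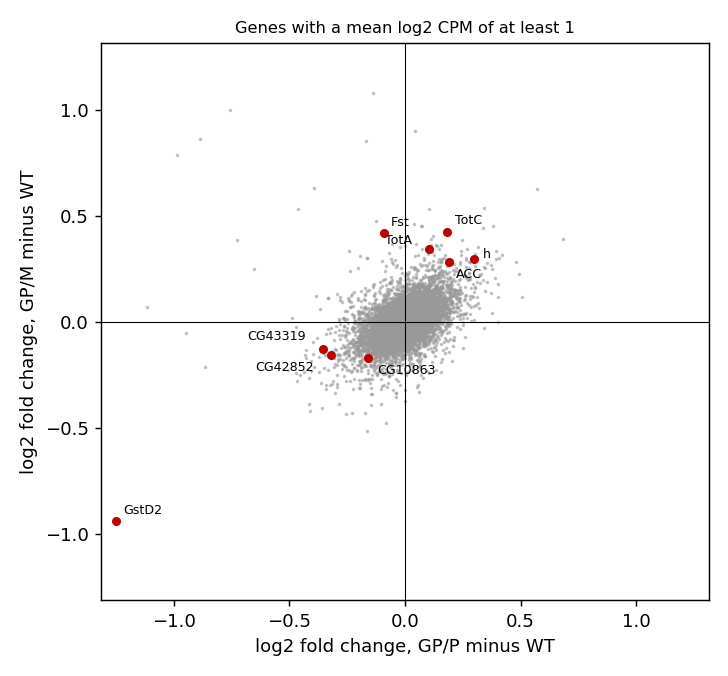
Each grey point is 1 of 11811 genes, with the log2 fold change of GP/P minus WT on the horizontal axis and of GP/M minus WT on the vertical axis. Red points mark 9 of the genes named in the text. The correlation of 0.475 lies below the 0.477 to 0.536 of unchanged groups with shared controls, in simulations that did not match the observed variances.

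Between the father's and the mother's line, GP/P against GP/M, no gene passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, with 220 genes at an unadjusted p under 0.05. Limma-voom and DESeq2 called 0 genes (214 and 93 unadjusted). The 10 genes with the smallest p had an adjusted p of 1. CG15630 was at 17.3 ± 0.522 CPM in GP/P and 14.6 ± 0.264 in GP/M (SD, n = 3 each), 1.18-fold and higher in 3 of 3 sets. The signalling gene hh was at 0.78-fold (5.03 ± 0.0751 against 6.44 ± 0.626 CPM), lower in 3 of 3 sets. CG12772 was at 1.16-fold, CG6066 at 1.29-fold, CG3548 at 1.21-fold and CG9123 at 1.18-fold. CG43405 was at 0.81-fold, CG32148 at 0.87-fold, CG13405 at 0.88-fold and CG42560 at 0.90-fold. Of genes with a mean log2 CPM of at least 1, 97.5% had an interval within 1.5-fold, and the simulated recovery was 94.0% at 1.5-fold. A single gene passed in the authors' deposited table, Fst, a cold-induced gene, with an adjusted p of 1.68e-06 and a moderated fold change of 0.83. Chosen after its values were seen, Fst was at 38.3 ± 15.1 CPM in GP/P and 54.3 ± 21.9 in GP/M, lower in 3 of 3 sets, with a 95% interval in log2 of -1.43 to 0.41 by edgeR without the block. Its log2 fold change of -0.51 was -0.858 without GP/P 1, -0.292 without GP/P 2 and -0.144 without GP/M 1. These fits had no block and left the groups uneven over the sets, so library and set cannot be told apart. DESeq2 with the replicate block called Fst on the 6 libraries of these groups and 0 genes on all 9 libraries, where Fst had an unadjusted p of 0.0018. The edgeR interval of Fst without the block contains the spread between sets.

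Camera with the preset correlation called 4 lists for GP/P against GP/M, and none with an estimated correlation. The antimicrobial peptide and peptidoglycan recognition list was lower in GP/P (26 of 27 members, median 0.808-fold, adjusted p = 1.81e-10; adjusted p = 0.632 with an estimated correlation). GP/M 3 stood apart in it: the attacin gene AttD, the member with the smallest p, was at 1.28, 0.905 and 2.66 CPM in GP/M 1, GP/M 2 and GP/M 3 and at 0.848 ± 0.316 in GP/P (SD, n = 3). Without GP/M 3 the list median was -0.116 in log2, against -0.307 with it, and it was -0.539 without GP/M 1 and -0.487 without GP/P 1. By set, the median of GP/P minus GP/M was 0.19, -0.282 and -0.909 in sets 1, 2 and 3. The male accessory gland list was lower in GP/P (46 of 54, 0.96-fold, adjusted p = 3.18e-06; adjusted p = 0.805 with an estimated correlation), with Sfp24C1 at 0.90-fold. This call ended when the trend with gene length was removed, as the median shrank from -0.058 to -0.022 (member SD 0.087 and 0.08; adjusted p = 5.03e-06 before and 0.417 after). The ribosomal list was called after that removal and not before it, as higher (median 0.028, adjusted p = 0.00905). With no removal it was called as higher without GP/P 3 (0.03, adjusted p = 0.0361) or GP/M 1 (0.041, 0.00302) and as lower without GP/M 3 (-0.05, 4.17e-06). The ovary and eggshell list was higher (9 of 11, 1.119-fold, adjusted p = 0.0289; adjusted p = 0.632 with an estimated correlation), with the yolk receptor gene yl at 1.43 ± 0.604 against 0.871 ± 0.0237 CPM; its log2 fold change of 0.73 was 0.316 without GP/P 3. The TCA cycle and respiratory chain list was higher (35 of 45, 1.016-fold, adjusted p = 0.0289; adjusted p = 0.805 with an estimated correlation), with the aconitase gene Acon at 1.06-fold. Among members with an exon length, removal of the length trend took the TCA median from 0.033 to 0.038 (adjusted p = 0.0264 and 2.56e-06 by camera with the preset correlation). The ovary median went from 0.162 to 0.186 (0.0264 and 0.0141 by the same test). No list member passed over all genes or adjusted over the list alone. With the replicate block the count of genes stayed at 0 (592 at an unadjusted p under 0.05), 1 list member, AttD, passed adjusted over the list alone, and 7 lists were called. The added lists were amylases and maltases (adjusted p = 0.0197, higher), glycolysis (0.0388, higher) and testis (0.0388, lower), led by Mal-A5 (1.03-fold), Pgi (1.05-fold) and janB (0.93-fold). Without the block, removal of the length trend took the medians of these lists from 0.047, 0.014 and -0.031 to 0.041, 0.012 and -0.016. With the block the smallest adjusted p was 0.643 under an estimated correlation and 0.577 under fry. The TCA cycle call was lost without WT 2, GP/P 1, GP/P 2 or GP/M 3 (medians 0.022, 0.02, 0.015 and -0.01; adjusted p = 0.0549, 0.282, 0.128 and 0.456). The ovary call was lost without GP/P 3, GP/M 1 or GP/M 2 (medians 0.105, 0.16 and 0.14, against 0.162; adjusted p = 0.0985, 0.0724 and 0.0514), and the accessory gland call without GP/M 2 (median -0.027, against -0.058; adjusted p = 0.0793). The TCA median of 0.023 rose to 0.035, 0.049 and 0.045 without GP/P 3, GP/M 1 and GP/M 2. Of the other leading members, AttD went from -0.934 to -0.372 without GP/M 3, janB from -0.103 to -0.066 without GP/M 2, Pgi from 0.069 to 0.105 without GP/P 1, and Mal-A5 from 0.048 to 0.01, 0.073 and 0.025 without GP/P 2, GP/P 3 and GP/M 3. Without GP/M 3, 10 lists were called, and edgeR called 1 gene, the non-coding CR43263 (adjusted p = 0.0409), which did not pass the filter when all libraries were used.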

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

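The tests of the male share, of the male tract, of the length trend as the whole cause and of GP/M 3 were chosen after the results were seen. Lists whose difference from WT itself differed between the lines of descent, by camera with the preset correlation on GP/P against GP/M, were antimicrobial peptides (adjusted p = 1.81e-10), male accessory gland (3.18e-06), ovary and eggshell (0.0289) and the TCA cycle and respiratory chain (0.0289). None was called with an estimated correlation. The accessory gland call ended when a trend with gene length was removed (median -0.058 before and -0.022 after, member SD 0.087 and 0.08, adjusted p = 0.417). The ovary call rests on 11 tested members that were scarce, and it was lost without GP/P 3, GP/M 1 or GP/M 2. In all 3 sets CG15630 lay above WT in GP/P (mean log2 difference 0.112) and below it in GP/M, and CG43405 lay below WT in GP/P (-0.128) and above it in GP/M; the differences of this kind were not tested apart from the contrast of both lines, where each had an adjusted p of 1 by edgeR.

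The antimicrobial list was lower in GP/P than in GP/M, with a median of -0.307 in log2. By set the median difference was 0.19, -0.282 and -0.909 in sets 1, 2 and 3. Their mean was -0.334 with an SD of 0.551 (n = 3 sets), so the difference did not exceed the spread between sets. A trend with gene length accounted for little of the list median in these libraries. After its removal the mean over the sets was -0.341 with a standard error of 0.358. Among members with an exon length the median was -0.331 before and -0.296 after that trend was removed, a mean shift of 0.05 over the sets with a standard error of 0.028 (n = 3 sets). GP/M 3 may hold most of the difference: without it the median was -0.116, although the list was still called with the preset correlation (adjusted p = 0.0309). An immune response in the flies of that library, or a difference between the lines of descent, stays open as untested.

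The male accessory gland list was lower in GP/P than in WT, with a median of -0.090 among members with an exon length. Over all members the difference by set was -0.187, -0.118 and 0.023 in sets 1, 2 and 3. Their mean was -0.094 with an SD of 0.107 (n = 3 sets), so it did not exceed the spread between sets before any removal. The length trend may account for part of the median of -0.090, since the median after its removal was -0.044. That is just past the bound set beforehand, a share of 0.5 of the median. Whether it is the whole cause cannot be told apart. The list was still called afterwards with the preset correlation (adjusted p = 8.50e-05), but the mean left over the sets was -0.046 with a standard error of 0.045 (n = 3 sets), and with an estimated correlation the list was not called even before the removal (adjusted p = 0.789). Under an assumed level in females, the values argue against a lower share of males, with females in their place. As general background, females express the yolk protein genes Yp1, Yp2 and Yp3 at a high level. The highest value of the 3 in a GP/P library was 12.2 CPM (13.4 in WT), and 6.1% of females would bring 59.6 CPM if these genes ranked with the 100 most abundant here. That level, 975 CPM at rank 100, was not measured in females. A smaller male tract as a whole cannot be told apart: the accessory gland list lay below the testis list by a mean of -0.079 over the sets, with a standard error of 0.052 (n = 3 sets), and a difference between the groups in the gland also stays open.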

How the results depend on the processing

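Tests chosen after the results were seen were the split counts for genes and the DESeq2, voom, camera and fry fits with the replicate block, apart from camera with the preset correlation. The count of 0 genes was unchanged in all 4 comparisons under other size factors, other filters, DESeq2, limma-voom, the replicate block, only the groups compared and stricter thresholds, and the shared count stayed at 0 there too. DESeq2 with the block on all 9 libraries called 1 gene for GP/P against WT, CG43319 (adjusted p = 0.00966), and 0 elsewhere. On only the groups compared, DESeq2 with the replicate block called 4 genes for GP/M against WT and 1 for GP/P against GP/M. The log2 fold changes were nearly the same as on all 9 libraries (TotA 0.335 and 0.339, Fst -0.502 and -0.503). The fits thus differ in the estimated spread, and why it differs was not tested. Leaving out 1 library gave 0 to 1 genes in each of the 4 comparisons and 0 to 1 shared genes. The 1 gene was GstD2 without WT 3 in the comparisons with WT, and CR43263 without GP/M 3. With the replicate block in camera the lists called were 12 for GP/P against WT, 7 for GP/M against WT and 7 for GP/P against GP/M, against 4 each without it, and 9 against 6 for both lines together. No list called without the block was lost with it, and members passing adjusted over the list alone rose from 0 to 14, 4, 1 and 10. An estimated correlation and fry left 0 lists in every comparison, with or without the block. Camera with an estimated correlation could miss a large shift. Between sets 3 and 1 it left the ribosomal list uncalled (adjusted p = 0.297), where 80 of 93 members passed, all lower. A lack of calls with it therefore does not show that a list is unchanged. That list had the highest estimated correlation, 0.83 for GP/P against WT without the block, so the example may not hold for other lists. The accessory gland and antimicrobial lists were estimated at 0.47 and 0.31 there. Their adjusted p with the preset of 0.01 thus rest on a correlation far below the estimated one. Leaving out 1 library gave 4 to 17 lists for GP/P against WT, 1 to 10 lists for GP/M against WT, 3 to 10 lists for GP/P against GP/M, 4 to 11 lists for both lines together. These fits had no block, so part of the range may come from groups left uneven over the sets. Of 107 values of named genes, 99 kept their sign under every alternative. Leaving out 1 library moved AkhR (GRHR) from -0.066 to 0.069 for GP/P against WT, -0.098 to 0.071 for GP/M against WT, -0.071 to 0.097 for GP/P against GP/M and -0.059 to 0.062 for both lines, and limma-voom gave 0.001 for GP/P against WT. It moved bmm from -0.008 to 0.165, -0.026 to 0.126 and -0.073 to 0.121 in the 3 pairwise comparisons, and Hsl (CG11055) from -0.008 to 0.037 for GP/M against WT. The TCA cycle median ranged from -0.01 to 0.049 for GP/P against GP/M and the ribosomal median from -0.072 to 0.031 for both lines. The planned pseudocount alternative does not apply to counts.

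Of other splits of the libraries, 3 against 3 gives 10, too few for a share under 0.05. The real split gave 0 genes in each pairwise comparison, and the highest other gave 1, 89 and 0 for GP/P against WT, GP/M against WT and GP/P against GP/M. It gave 4 lists in each, and the highest other gave 16, 19 and 13; as many lists came from 9, 10 and 9 of the 10 splits. For both lines together chance cannot be excluded for the lists: 56 of 84 splits gave as many (6 real, highest other 18). Of these 84 splits 57 mix the sets, so that share leaves out the pairing. A real count of 0 genes is matched by every split by construction (10 of 10 in the pairs, 84 of 84 for both lines, 100 of 100 drawn for shared genes), so for genes the counts decide nothing. The highest other was 1576 genes for both lines and 370 shared. The split with 1576 genes sets the 3 libraries of set 3 against the rest, which points to a structure by set. Among splits that part the sets as the real one does, the highest other counts were 0 genes in every comparison and 5, 4, 6 and 8 lists in the order GP/P against WT, GP/M against WT, GP/P against GP/M and both lines; the remaining splits set libraries of different sets against each other. Recovery of 1.25-fold changes in the simulations, 46.3% to 58.2%, limits what the depth and spread can show.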

Other observations

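The test of the set term was chosen after the data were seen. The experimental sets differed from each other in many genes, while edgeR called no gene in the comparisons of the groups with all libraries. In edgeR's blocked fit 2024 of 12913 genes differed between sets, and 1515 were higher and 894 lower in set 3 than in set 1. Npc1b, a sterol transporter gene, was higher in set 3 by 0.68 in log2 (SE 0.047, adjusted p = 1.41e-07) and Npc2e, of the same pathway, by 1.32 (SE 0.125, adjusted p = 5.34e-06); both were chosen after their values were seen. Of the lists, 80 of 93 ribosomal protein genes were past the threshold and lower in set 3 than in set 1 (median -0.155, adjusted p = 5.39e-34 by camera). In the TCA cycle and respiratory chain list 18 of 45 passed, 1 of them higher (median -0.081). Neuron genes (11 of 20 past the threshold, all higher, median 0.185), chromatin modifiers (11 of 31, all higher, 0.137) and trehalose, glycogen and gluconeogenesis genes (7 of 15, all higher, 0.12) lay on the other side. None of the lists was called with an estimated correlation (adjusted p of at least 0.297).

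The set difference followed gene length. The median of set 3 minus set 1 was -0.098 in the fifth of genes with the shortest exons (median length 678 bases) and 0.135 in the fifth with the longest (5197 bases). For GP/P minus WT the same medians were -0.049 and 0.039, and for GP/M minus WT -0.01 and 0.012. A length bias between libraries, as from RNA quality or library preparation, is a candidate explanation for part of it: with the length trend removed, 850 genes still differed between sets, of 1914 before (44.4%), under the bound, a share of 0.5, set before that test was run. What holds the remaining genes apart stays open, and a difference between the experiments in food, age or handling was not tested.

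Without the block, groups explained 20.51% of the variance of log2 CPM and replicate numbers 37.32%, where 25% each is expected with no effect. The labels used here give no sex. Male seminal fluid genes were abundant and yolk protein genes scarce in the control libraries: Acp36DE was at 1600 ± 64.1 CPM and Yp1 at 3.12 ± 1.79 CPM in WT (SD, n = 3).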
